A study of Mus musculus with 96 samples.

How the data were processed

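The study exposed mouse primary bone marrow dendritic cells to 5 ligands of Toll-like receptors and sampled them over a day. The ligands carry the short names Lps, Pic, Pam, Cpg and Grd in the labels. From knowledge of the study, and not from the labels, they are taken here as lipopolysaccharide (a TLR4 ligand), the double-stranded RNA analogue poly(I:C) (TLR3), a synthetic bacterial lipopeptide (TLR2), CpG oligonucleotides (TLR9) and gardiquimod (TLR7). Per the labels, total RNA was labelled with biotin and hybridised to one-colour Affymetrix mouse arrays.

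Each ligand was sampled at 9 times from 0.5 to 24 h with 2 arrays per time, except that Cpg had 1 array at 16 h and 1 at 24 h. This gave 18 arrays each for Lps, Pic, Pam and Grd and 16 for Cpg. Unstimulated cells had 8 arrays, 1 each at 0, 1, 2, 4, 6, 8, 12 and 24 h. All 96 arrays lay on 1 plate. Each time of Lps, Pic, Pam and Grd had its own plate column, from 1 to 9, and all Cpg and unstimulated arrays lay in columns 10 to 12. An effect of place thus cannot be told apart from time, or from ligand against unstimulated cells for these 4 ligands. Each of these ligands also had plate rows of its own in these columns, and Cpg lay in other columns. Place thus cannot be told apart from ligand between ligands either. Among the unstimulated arrays the plate column rose with time, except that 6 h lay in a later column than 8 h. The labels do not say whether the arrays of a group came from separate cultures, so all p-values measure only the spread between these samples, which may be technical.

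The deposited values are intensities on a linear scale for 18858 probe sets. The submitters' processing notes name RMA, a method that corrects background, normalizes between arrays and summarizes probes, and its version is not given in the sources used here. The step that returned the values to a linear scale and set a floor of 20 is also not given there. The highest intensity was 16401.5. Between 33.1% and 34.6% of the probe sets of an array lay at the floor, and the median intensity per array ranged from 48.75 to 59.5. The floor limits what can be measured: a gene at 20 on all arrays of a group has only an upper bound there, and its change is given as at least so many fold. The number of arrays limits the precision of each mean.

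Probe sets were named from the platform annotation. It gave 1 symbol for 15044 probe sets, several for 257 and listed no gene for 3557. Symbols were checked through Entrez identifiers against the RefSeq gene table of assembly GRCm38.p6, in which 15024 probe sets were matched and 0 symbols changed. No genome build is given for the values, so no coordinates are printed. The 4409 probe sets at the floor on all arrays were left out, which left 14449. For each gene the probe set with the highest mean over all 96 arrays was kept, and probe sets with several symbols or none were kept as themselves but not named. This gave 10543 items for testing, made of 7741 named genes and 2802 unnamed probe sets, all called genes in the counts below.

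Values were analysed as log2(value + 1), with no further normalization. A fold change on this scale understates the change of dim genes. One linear model in limma 3.58.1 under R 4.3.3 fitted a mean for each of the 45 ligand and time groups and 1 mean for the 8 unstimulated arrays, with 50 residual degrees of freedom and empirical Bayes moderation. Times were grouped into an early window (0.5, 1 and 2 h), a middle window (4, 6 and 8 h) and a late window (12, 16 and 24 h). Each ligand window was compared with the 8 unstimulated arrays, and the ligands were compared with each other in the middle window. A window held 6 arrays of a ligand, or 4 for Cpg in the late window. The change of the unstimulated cells with time was fitted on log2(hours + 1) over their 8 arrays alone. A gene was called when its Benjamini-Hochberg adjusted p was under 0.05 and its log2 difference was at least 1 in size. Errors given as ± after a log2 difference are standard errors from this model. Tests were two-sided.

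Which genes are named was fixed before the data were examined, as were the gene lists, the tests of the comparisons and all alternatives but 2. The tests of explanations in the closing part, and the random regroupings of arrays, were chosen after the results were seen. For each ligand window the rule took the 6 largest rises and 4 largest falls among called genes whose every array in the window lay on 1 side of the unstimulated mean. For each ligand pair it took the 5 largest differences each way among called genes whose arrays did not overlap. It also took the 5 largest trends each way in the unstimulated cells, up to 4 members of each list with the largest differences, and a fixed panel of cytokine, chemokine, receptor and immediate-early genes. Of the panel, Ccr7 was not analysed here. Where a named gene had other probe sets, these were compared. Of 1125 called pairs of a named gene and a comparison, 369 had another measured probe set. In 321 such comparisons of probe sets the other was called the same way, in 136 it pointed the same way without a call, in 19 it showed no difference, and in 3 it pointed the other way without a call.

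In all, 27 gene lists were tested in 25 comparisons with camera from limma at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over all 675 tests. Of these, 237 were called, and 96 of them were also called with a correlation estimated from the data. The test fry, which asks whether the members move one way on balance and does not compare them with other genes, called 511. The median, the mean and the test of a list differed in sign in 97 tests. The numbers of called list members were the same when adjusted over the list alone, with 0 of the 675 tests differing.

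The model was tested on simulated data with the unstimulated means and fitted spread of the real genes. The changed genes were drawn from those at least 3 log2 units above the floor, so recovery of dimmer genes was not tested. In simulations of Lps in the middle window, Cpg in the late window and Pic against Pam, 100 of 100 genes changed by 1.5 log2 units and 100 of 100 changed by 3 were recovered each time, with 0 false calls among the unchanged genes of the 10543. The unstimulated arrays had no change with time in these simulations, so the effect of a drifting baseline was not tested. In the simulated unstimulated trend 200 of 200 genes changed by 3 were recovered, with 1 false call. Of 100 unchanged random lists, camera gave 1 an unadjusted p under 0.05. The simulated genes varied independently of each other, so camera was not tested on lists of correlated genes.

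The alternatives tried were quantile normalization, centring each array on its median, log2(value + 16), a filter on dim probe sets, the mean over all probe sets of a gene, moderation with trend and robust options, array weights, the adjusted p alone, limma's treat, unstimulated arrays matched in time or with a linear trend, the arrays of each comparison alone, the replicate number as a block, windows shortened by their first or last time, and each array left out in turn. For Cpg in the late window the 12 h arrays were also taken alone, and the unstimulated trend was also fitted on hours, with the spread of all 96 arrays, and without genes at the floor. Tables were handled in Python 3.11.15 with pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.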

Results

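Expression was measured in mouse bone marrow dendritic cells at 9 times after addition of 1 of 5 Toll-like receptor ligands, on 96 arrays, to ask how the response differs between ligands and over time. There were 18 arrays each for Lps, Pic, Pam and Grd, 16 for Cpg and 8 for unstimulated cells. Arrays of the same ligand and time correlated with Pearson's r between 0.9853 and 0.9982 across genes, which are not independent replicates. The median standard deviation of the log2 difference between such arrays was 0.165. The first 3 principal components held 36%, 20% and 15% of the variance. Every value is an intensity with a floor of 20, so at 20 a transcript was not distinguishable from background.

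**Figure D1:**
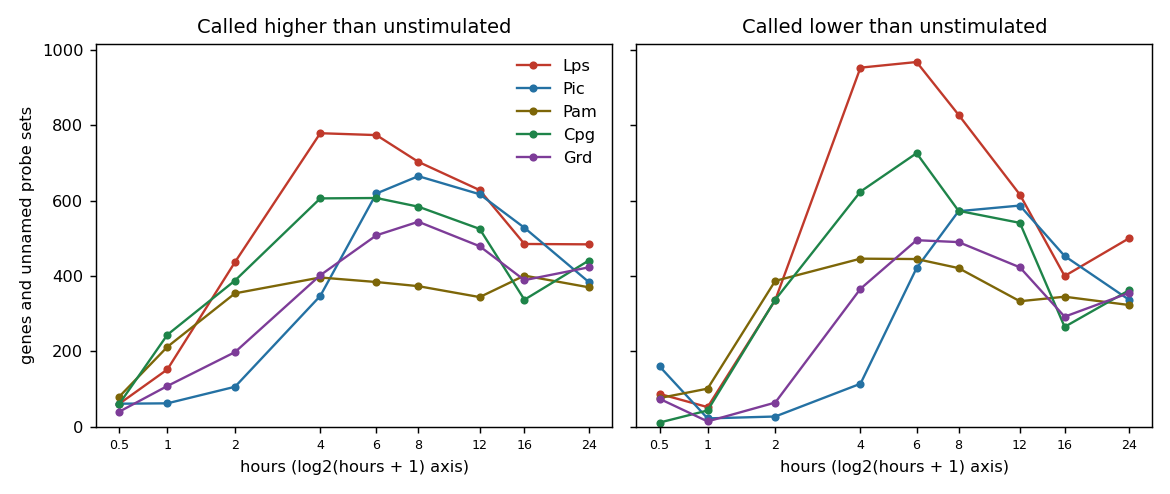
Number of genes called higher and lower than in the 8 unstimulated arrays (vertical axis) at each time in hours (horizontal axis), for each of the 5 ligands with 2 arrays per point, or 1 for Cpg at 16 and 24 h. Lps reached 1742 genes at 6 h and Pic 1237 at 8 h, while Pam had 842 at 4 h.

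Within 2 h of Lps, transcripts of inflammatory mediators were far above their unstimulated levels. Cxcl1, which encodes a neutrophil-attracting chemokine, lay at the floor in all 8 unstimulated arrays and rose at least 42.0-fold, to a mean intensity of 1614 (n = 6). Tnf rose by 5.21 ± 0.17 on the log2 scale, Il6 by 4.96 ± 0.18, the neutrophil chemokine gene Cxcl2 by 5.11 ± 0.26 and Nfkbiz, which encodes a nuclear regulator of NF-kB target genes, by 4.67 ± 0.14. Ptgs2, the inducible cyclooxygenase of prostaglandin synthesis, rose at least 30.5-fold. The cannabinoid receptor gene Cnr2 fell by 1.73 ± 0.13 and the glucocorticoid-induced gene Tsc22d3 fell by 1.68 ± 0.14. Adjusted p in limma for these genes ran from 2.7e-43 for Cxcl1 to 1.7e-14 for Tsc22d3. Each lay on 1 side of the unstimulated mean in 6 of 6 arrays, which the rule for naming the largest changes required. In all, 165 genes were higher and 58 lower, or 194 and 33 with each array centred on its median. Without the 0.5 h arrays 387 genes were called and without the 2 h arrays 136, and with a linear trend fitted to the unstimulated arrays 146.

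At 4 to 8 h of Lps the response was larger. Il6 reached a mean intensity of 6951 against 28.9 ± 14.5 (SD, n = 8) in unstimulated cells, a rise of 7.97 ± 0.18 on the log2 scale, and Ptgs2 rose at least 241-fold. Cxcl10, a chemokine gene induced by interferon, rose by 7.47 ± 0.16, and Ch25h, which encodes the enzyme making 25-hydroxycholesterol, by 6.01 ± 0.12. Among the falls were Vsir, an immune checkpoint receptor gene, at -3.85 ± 0.19, and the transcription factor genes Sox4 at -3.58 ± 0.13 and Egr2 at -3.28 ± 0.19. The size of the Sox4 fall rests on 1 probe set. The 4 others stood at -1.27, called, and at -0.42, -0.38 and 0, not called. These may be bounds set by the floor and then do not count against the size. In this window 741 genes were higher and 866 lower, or 955 and 536 with centred arrays, with adjusted p of 9.6e-22 or less for the genes named. At 12 to 24 h 492 were higher and 466 lower. Il6 was still 7.18 ± 0.18 above unstimulated cells, and Il12a, a subunit gene of interleukin-12, was at least 53.6-fold higher. The chemokine receptor gene Ccr2 fell by 5.48 ± 0.09 (-2.12 on a second probe set, also called, here and with Pam, Cpg and Grd) and the mannose receptor gene Mrc1 fell by 5.45 ± 0.11 (adjusted p = 7.4e-47 and 8.2e-42 in limma). Being the same with each of these ligands, the -2.12 is probably a bound set by the floor.

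The first 2 h of Pic changed fewer genes. Cxcl2 rose by 2.96 ± 0.26, Inhba, which encodes a subunit of activins, by 2.66 ± 0.31, the chemokine gene Ccl4 by 2.48 ± 0.21, Tnf by 2.38 ± 0.17 and Cxcl10 by 2.35 ± 0.16. Each rose in 6 of 6 arrays, as the naming rule required. Tlr8 fell by 1.63 ± 0.20 and Tsc22d3 fell by 1.26 ± 0.14. There were 66 genes higher and 24 lower (adjusted p from 6.4e-16 for Tnf to 3.7e-09 for Tlr8 among those named). The number called fell to 33, all higher, at 1 and 2 h against unstimulated arrays of the same times, a setting that also leaves out the 0.5 h arrays, which have no match. There Tlr8 stood at -0.23 and Tsc22d3 at -0.74, neither called. Without the 0.5 h arrays alone 81 genes were higher and 17 lower, and Tlr8 stood at -1.04, still called. With a linear trend in the unstimulated arrays 27 were higher and 3 lower, without the 2 h arrays 52 and 47, and with array weights 48 were called in all. The lower count of 24 became 13 without the unstimulated 24 h array, 42 without the 2 h array, and 37 without the 0 h or the 1 h array.

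At 4 to 8 h of Pic, Cxcl10 rose by 7.55 ± 0.16 to a mean intensity of 7882. Ifnb1, the gene of interferon-beta, lay at the floor in unstimulated cells and rose at least 57.8-fold, and the chemokine gene Cxcl11 rose at least 46.3-fold, on 1 of its probe sets, with the other at 0.34 and not called. The interferon-induced GTPase gene Iigp1 rose by 5.08 ± 0.19, Ch25h by 5.34 ± 0.12 and Il6 by 4.93 ± 0.18. Vsir fell by 2.95 ± 0.19 and Lpin1, a phosphatidate phosphatase gene, fell by 2.26 ± 0.12. Adjusted p was 8.3e-20 or less for each. In this window 517 genes were higher and 294 lower, or 639 and 193 with centred arrays. In the late window 476 were higher and 422 lower, or 577 and 327 when centred. Cxcl10 was then 6.57 ± 0.16 above unstimulated cells, and the interferon-induced exonuclease gene Isg20 was 4.95 ± 0.18 above. Mrc1 stood at -3.91 ± 0.11, Ccr2 at -3.82 ± 0.09 (-2.12 on a second probe set, called, probably a bound set by the floor) and the fibronectin gene Fn1 at -3.47 ± 0.10 (adjusted p from 1.6e-39 to 4.7e-35 for these falls).

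With Pam, the early rises were led by Cxcl1, at least 53.8-fold, Tnf at 5.49 ± 0.17, Nfkbiz at 5.31 ± 0.14, Il6 at 5.16 ± 0.18, Cxcl2 at 5.15 ± 0.26 and Ptgs2, at least 37.5-fold. Cnr2 fell by 1.66 ± 0.13 and Tmem140 fell by 1.58 ± 0.15. In the middle window Marco, a scavenger receptor gene of macrophages, rose by 5.61 ± 0.13 and Il6 by 7.61 ± 0.18. Falls were -3.65 ± 0.14 for the signalling regulator gene Rgs2, -3.56 ± 0.12 for the transcription factor gene Klf4 and -3.33 ± 0.10 for Eps8. In the late window Marco stood 7.01 ± 0.13 above unstimulated cells, Cxcl1 was at least 155-fold higher and Cxcl5, a neutrophil chemokine gene, at least 66.1-fold. Mrc1 fell by 5.40 ± 0.11 and Ccr2 fell by 4.84 ± 0.09. All adjusted p for these genes in limma were 9.2e-13 or less, the value for Tmem140, with n = 6 against 8. The counts were 174 higher and 77 lower early, 366 and 423 in the middle window, and 360 and 312 late. The Pam arrays of 2 h differed more than any other pair of the same ligand and time, with r of 0.9853 and 180 genes 2-fold apart. The early counts were 184 and 94 when the first of them was left out, and 175 and 66 when the second was. With centred arrays the early counts were 220 and 48 and the middle ones 431 and 328. Without the 0.5 h arrays 430 genes were called early, and with a linear trend in the unstimulated arrays 165.

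Cpg gave early rises of Tnf by 5.55 ± 0.17, Il6 by 5.21 ± 0.18, Cxcl2 by 5.17 ± 0.26 and Nfkbiz by 5.04 ± 0.14, with Cxcl1 at least 52.7-fold and Ptgs2 at least 42.7-fold higher. Cnr2 fell by 1.61 ± 0.13 and the transcription factor gene Nfe2 fell by 1.46 ± 0.13. In the middle window Il6 rose by 7.87 ± 0.18, Cxcl10 by 6.80 ± 0.16 and Il12b, the subunit gene shared by interleukin-12 and interleukin-23, by 5.70 ± 0.22. Sox4 fell by 3.46 ± 0.13, and the coactivator gene Ppargc1b fell by 3.37 ± 0.13. The 4 other probe sets of Sox4 stood between -1.27 and 0, as with Lps, and may be bounded by the floor. Late, with n = 4, Il6 was 7.22 ± 0.21 and Marco 6.27 ± 0.15 higher, while Mrc1 fell by 5.21 ± 0.13 and Ccr2 fell by 4.68 ± 0.10. Adjusted p in limma was 1.4e-13 or less for every gene named here. Early, 195 genes were higher and 31 lower. In the middle window 567 were higher and 583 lower, or 704 and 412 with centred arrays, and late 407 were higher and 341 lower. Early counts were 402 without the 0.5 h arrays and 144 without the 2 h arrays.

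In the first 2 h Grd changed fewer genes than Lps, Pam or Cpg. Cxcl2 rose by 4.82 ± 0.26, Tnf by 4.60 ± 0.17, Nfkbiz by 3.99 ± 0.14, Il6 by 3.92 ± 0.18 and Cxcl1 at least 22.3-fold, and Rgs2 fell by 1.46 ± 0.14. By 4 to 8 h Il6 had risen by 7.70 ± 0.18, Tnf by 6.04 ± 0.17 and Cxcl10 by 5.89 ± 0.16, while Vsir fell by 3.69 ± 0.19 and Klf4 fell by 3.24 ± 0.12. At 12 to 24 h Cxcl1 was at least 155-fold, Marco 6.58 ± 0.13 log2 units and Lox, a collagen crosslinking enzyme gene, 6.06 ± 0.11 log2 units above unstimulated cells, and Mrc1 fell by 5.31 ± 0.11. Adjusted p in limma was 5.4e-12 or less for each, with n = 6. The counts were 101 higher and 18 lower early, 478 and 413 in the middle window, and 405 and 304 late. With a linear trend in the unstimulated arrays 69 genes were called early, and Rgs2 stood at -0.97 without a call. The lower count of 18 became 11 without the unstimulated 24 h array, 31 without the 2 h array and 28 without the 0 h array.

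**Figure D2:**
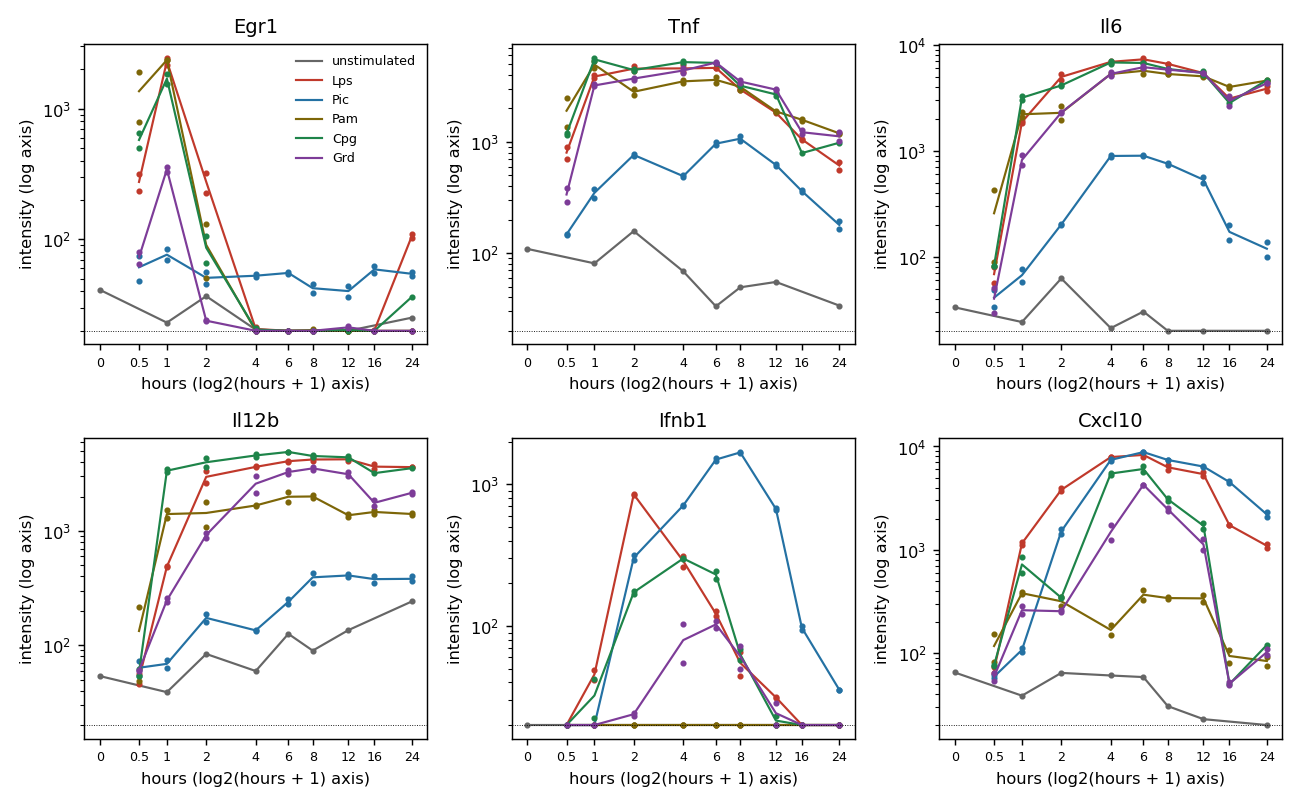
Intensity on a log axis (vertical) against time in hours (horizontal) for Egr1, Tnf, Il6, Il12b, Ifnb1 and Cxcl10, with points for arrays, lines for ligand means and a dotted line at the floor of 20. Egr1 peaks at 1 h, and Ifnb1 peaks at 2 h with Lps and at 8 h with Pic while it stays at the floor with Pam.

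The fixed panel showed the order of the response. Egr1, an immediate-early transcription factor gene, peaked at 1 h with every ligand, at mean intensities of 2351 with Pam, 2306 with Lps, 1693 with Cpg, 343 with Grd and 76.4 with Pic, against 25.8 ± 8.42 (SD, n = 8) in unstimulated cells. Ifnb1 peaked at 850 with Lps at 2 h, at 299.8 with Cpg at 4 h, at 103 with Grd at 6 h and at 1682 with Pic at 8 h, and lay at the floor with Pam at every time. Il12b peaked at 4917 with Cpg, 4239 with Lps, 3531 with Grd, 2004 with Pam and 408 with Pic, against 104 ± 65.2 unstimulated. Cd40, a costimulatory receptor gene, reached 4518 with Lps and 1934 with Pam, against 103 ± 36.1. Nos2, the inducible nitric oxide synthase gene, peaked at 197 with Lps and lay at the floor with Pam. Il10 did not exceed 48.9 with any ligand. Tlr9, the receptor of CpG DNA, had a highest mean of 22.5, so its level could not be measured here. The receptor gene Tlr3 reached 641 with Pic, 496 with Lps and 355 with Cpg against 54.4 ± 10.7, and in the middle window it rose by 3.21, 2.94 and 2.30 log2 units with these ligands and stood at -1.25 with Pam. Its other probe set gave 1.63, 1.68 and 1.39 for these rises, and -0.14 with Pam, not called.

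**Figure D3:**
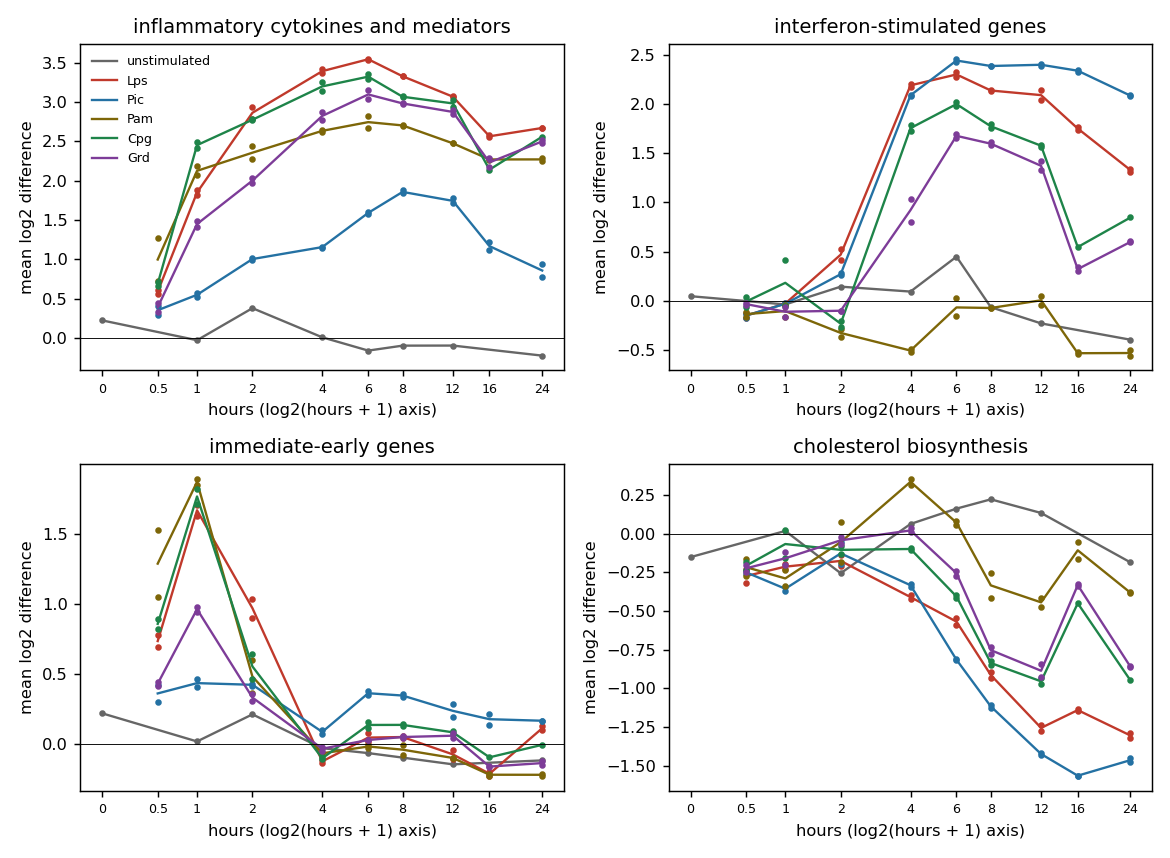
Mean log2 difference from the unstimulated arrays (vertical axis) against hours (horizontal axis) for inflammatory mediators, interferon-stimulated genes, immediate-early genes and cholesterol biosynthesis, with points for arrays and lines for ligand means. At 6 h the mean of the interferon-stimulated genes was 2.45 with Pic and 2.30 with Lps, and with Pam its highest value was 0.004, at 12 h.

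Interferon-stimulated genes, 42 of them measured, separated the ligands. In the middle window 34 rose with Pic, 32 with Lps, 31 with Cpg and 26 with Grd, and none of these ligands had a fall among them. The adjusted p from camera were 6.5e-36, 1.1e-25, 5.1e-26 and 2.5e-22, or 0.0042, 0.019, 0.018 and 0.03 with an estimated correlation. Examples with Lps were Iigp1 at 4.80, Cmpk2 at 4.44 and Isg20 at 4.39. With Pam, Cxcl10 rose by 2.71 while 6 members fell, among them Ifit3 by 1.32 and Oas3 fell by 1.27, and the list was not called (median -0.27, adjusted p = 0.22). Late, 35 members were higher with Pic (median 1.84, p = 1.7e-33, 0.0061 as adjusted p with an estimated correlation) and 29 with Lps (median 1.33, p = 2.9e-25, 0.02 as adjusted p with an estimated correlation). With Cpg 18 and with Grd 12 were higher (p = 2.1e-16 and 1.7e-11), and these calls were lost at adjusted p = 0.072 and 0.16 with an estimated correlation. In the late Pam window 7 members fell, including Ifit2 by 2.39 and Iigp1 fell by 2.02 (-0.74 on its other probe set, not called), and Cxcl10 rose by 1.72. The list was then lower (median -0.31, p = 0.0077), a call lost at adjusted p = 0.62 with an estimated correlation, and with Pam at 12 and 24 h against the unstimulated arrays of these times, which also leaves out 16 h, the median was -0.11. Leaving out 16 h alone gave -0.20.

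Inflammatory cytokines and mediators, with 23 members measured, were higher in every ligand window. Early, 13 rose with Lps and with Cpg, 12 with Pam, 10 with Grd and 6 with Pic. In the middle window 20 rose with Lps and Cpg, 18 with Grd, 16 with Pam and 13 with Pic, with median log2 differences of 2.52 for Cpg, 2.44 for Pam and 1.29 for Pic. Adjusted p in camera was 5.1e-06 or less in all 15 windows, and at most 0.024 with an estimated correlation. Genes of the NF-kB pathway, 22 measured, were also higher in all 15 windows, from 2 members called with Pic early to 12 with Lps in the middle window (adjusted p = 1.9e-06 or less, at most 0.046 with an estimated correlation), led by Nfkbiz, the apoptosis regulator gene Cflar and Tnfaip3, which encodes an inhibitor of NF-kB signalling. Of 19 chemokine genes, 12 rose with Lps and Cpg in the middle window, 10 with Grd and 8 with Pic and Pam (adjusted p = 2.1e-07 or less, at most 0.019 with an estimated correlation).

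Immediate-early genes, 23 measured, were higher early with each ligand: 12 rose with Lps and Pam, 11 with Cpg, 5 with Grd and 4 with Pic. Adjusted p in camera ran from 5.3e-19 with Pam to 5.7e-08 with Pic, or 0.00017 and 0.022 with an estimated correlation. Egr1 rose by 4.59 with Pam and 1.27 with Pic, and the small Maf gene Maff by 2.84 and 1.39. Of 19 negative feedback regulators, 10 rose early with Lps, Pam and Cpg, 7 with Grd and 3 with Pic, with Socs3, a suppressor of cytokine signalling, up by 4.10 with Pam (adjusted p = 1e-06 or less, at most 0.031 with an estimated correlation). Dendritic cell maturation genes, 19 measured, were higher with each ligand in the middle window. There 11 rose with Lps, 10 with Pic, 9 with Cpg and 6 with Grd and Pam. The adjusted p were 1.4e-08, 1e-09, 2.4e-08, 9.2e-08 and 1.2e-06, or 0.037, 0.024, 0.041, 0.05 and 0.078 as adjusted p with an estimated correlation, which loses the call for Pam and for Grd. Cd40 rose by 5.39 with Lps and 4.15 with Pam, and the costimulatory ligand gene Cd80 by 3.13 and 1.95, with one of its other probe sets at 1.11, called, and 0.43, not called.

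The ligands were set against each other at 4 to 8 h, with 6 arrays each and no unstimulated arrays in the contrast. Lps, Pic, Pam and Grd lay in different plate rows, and Cpg in other columns, so an effect of place cannot be told apart from ligand here. Pam stood below the other 4 ligands in interferon-stimulated genes. Of the 42 measured, 39 were higher with Lps than with Pam, 39 with Pic, 37 with Cpg and 31 with Grd. Adjusted p in camera were 1.8e-46, 1.9e-39, 1.2e-61 and 2e-77, or 0.0012, 0.0029, 0.00017 and 4.8e-05 with an estimated correlation. Iigp1 was 6.08 ± 0.21 log2 units higher with Lps than with Pam, and Isg20 was 5.05 ± 0.19 higher. Genes higher with Pam than with Lps included Egr2 at 2.99 units, as the difference of Lps from Pam was -2.99 ± 0.21, and the growth arrest gene Gadd45a at -2.68 ± 0.15. Lps had 442 genes above and 206 below Pam. Pam had 38 above and 280 below Cpg, led by the growth factor gene Ereg at 2.28 ± 0.14 and Iigp1 at -5.47 ± 0.21. Against Grd, Pam had 4 genes above and 151 below. Of those above, the transcription factor gene Gfi1 stood at 1.43 ± 0.08, the phospholipase gene Pla1a at 1.10 ± 0.19 and the hepcidin gene Hamp at 1.02 ± 0.06. Hamp was not called on log2(value + 16), at 0.69, or without either the second 4 h array of Pam (0.99) or the second 6 h array of Grd (0.998 log2 units).

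Pic differed from the other ligands in both directions. Ifnb1 was at least 57.8-fold above Pam, 3.95 ± 0.10 log2 units above Grd and 2.89 ± 0.10 above Cpg, and the difference of Lps from Pic was -3.28 ± 0.10. Ifna2 and Ifna4 lay at the floor with Lps and were at least 26.2-fold and at least 7.72-fold higher with Pic, although interferon-alpha genes are close copies that an array may not separate. Lower with Pic were Cxcl1, at -6.89 ± 0.11 against Pam and -6.39 ± 0.11 against Cpg, and Ptgs2, at -3.82 ± 0.13 and -4.23 ± 0.13. Of the 23 inflammatory mediators, 17 were higher with Lps than with Pic (median 1.67, adjusted p = 1.1e-21, 1.8e-05 as adjusted p with an estimated correlation), and 15 were lower with Pic than with Cpg (p = 2.2e-16, 8.4e-05 as adjusted p with an estimated correlation). Against Grd 12 were lower and 1 higher (camera p = 1.2e-09, 0.0029 as adjusted p with an estimated correlation). Against Pam 12 were lower and 1, the cytokine gene Il15, was higher at 3.07 (p = 0.0005, lost at adjusted p = 0.091 with an estimated correlation). Lps had 202 genes above and 189 below Pic. Pic had 555 above and 312 below Pam, 179 above and 181 below Cpg, and 233 above and 191 below Grd.

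Lps had 35 genes above and 14 below Cpg. Plagl1, a zinc finger gene, was at least 7.72-fold higher, Cxcl11 was 2.95 ± 0.06 (0 on its other probe set) and the histamine-forming enzyme gene Hdc 1.86 ± 0.09 log2 units higher, and Cxcl5 stood at -1.56 ± 0.09. Lps had 146 above and 64 below Grd, or 182 and 37 with centred arrays. Cxcl11 was 4.11 ± 0.06 higher on the same probe set, the homeobox gene Lhx2 3.43 ± 0.07 higher and Nos2 at least 6.94-fold higher than with Grd, and Egr2 stood at -2.60 ± 0.21. Cpg had 34 above and 9 below Grd, with Pla1a 2.20 ± 0.19 and the chemokine gene Ccl12 1.88 ± 0.10 higher and Ereg at -2.32 ± 0.14. On log2(value + 16) this last pair had 21 called genes. Interferon-stimulated genes were higher with Lps than with Cpg by a median of 0.23 (2 members called, Cxcl11 and Cxcl9, adjusted p = 7.6e-12), a call lost at adjusted p = 0.15 with an estimated correlation. They were also higher with Lps than with Grd (9 members called, p = 4.5e-22) and with Cpg than with Grd (3 members, p = 2.8e-20), at adjusted p = 0.031 and 0.04 with an estimated correlation.

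Genes of cholesterol biosynthesis, 17 measured, were lower late with Pic (11 fell, median -1.64, adjusted p = 1.2e-10) and Lps (11 fell, median -1.25, p = 1.3e-09), at adjusted p = 0.024 and 0.035 with an estimated correlation. With Pic, squalene epoxidase (Sqle) stood at -2.58, the sterol carrier gene Stard4 at -2.50 and Cyp51 at -2.27. With Cpg 5 fell and with Grd 3 (p = 3.2e-07 and 1.3e-06, lost at adjusted p = 0.079 and 0.1 with an estimated correlation). Late with Pam no member was called, with Dhcr7 at -0.85 and a median of -0.31 (p = 0.019, lost at adjusted p = 0.47 with an estimated correlation). Small shifts over whole lists were seen late for oxidative phosphorylation (45 genes) and cytosolic ribosomal proteins (38 genes). The oxidative phosphorylation medians were -0.38 with Lps, -0.46 with Pic, -0.37 with Cpg and -0.43 with Grd (adjusted p = 1.7e-09, 2.6e-11, 2.5e-10 and 4.1e-12, or 0.042, 0.024, 0.032 and 0.019 with an estimated correlation). The ribosomal medians were -0.38, -0.29, -0.26 and -0.28 (p = 6.7e-14, 5.5e-10, 2.7e-11 and 3.3e-12, or 0.013, 0.042, 0.029 and 0.021 with an estimated correlation). With Pam the medians were -0.23 for oxidative phosphorylation and -0.15 for ribosomal proteins (camera p = 1.3e-05 and 3.3e-05, lost at adjusted p = 0.16 and 0.2 with an estimated correlation). Of their members, the subunit gene Ndufs8 alone was called late, with Pic, at -1.08 on 1 probe set (-0.98, -0.84 and -0.68 on the 3 others, not called). The glycolysis list, 15 genes, was not called in any window, although Aldoc, an aldolase gene, was lower late with Pic at -2.83 and with Lps at -2.45 (-0.96 and -0.97 on its other probe set, not called).

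Of 12 genes of MHC class II presentation, 4 fell late with Grd (median -0.60, adjusted p = 3.9e-07, 0.018 as adjusted p with an estimated correlation) and 4 with Pam (median -0.48, p = 1.1e-05, 0.039 as adjusted p with an estimated correlation). Of this list, H2-DMa stood at -2.78 and -2.41. The list was also lower late with Cpg and Lps (3 and 2 members fell, p = 9.8e-05 and 0.0042), calls lost at adjusted p = 0.069 and 0.2 with an estimated correlation. MHC class I presentation, 13 genes, was higher late with Pic (median 0.64, p = 6.8e-05), where the immunoproteasome genes Psmb9 and Psmb10 rose by 1.16 and 1.09, a call lost at adjusted p = 0.091 with an estimated correlation. Of 21 Toll-like receptor and adaptor genes, 6 rose and 1 fell in the middle Lps window (p = 0.015, lost at adjusted p = 0.053 with an estimated correlation), with Tlr1 up by 2.07 and Tlr4, the receptor of Lps, at -1.61. Cell cycle genes, 35 measured, were lower late with Pic, where 10 fell, the cyclin gene Ccna2 among them (-1.53, and -0.92 on another probe set, not called; p = 0.00026, lost at adjusted p = 0.13 with an estimated correlation). In the middle Pam window Tyms, which encodes thymidylate synthase, rose by 2.44 on 1 probe set (0.31 on the other, not called) and Mki67 by 1.54 while the centromere gene Cenpa fell by 1.85. Of 18 endoplasmic reticulum stress genes, Asns, asparagine synthetase, rose late with every ligand, from 2.04 with Lps to 2.73 with Pic, and the list was not called late. Lysosome genes, 18 measured, were lower in the middle Lps window (median -0.37, p = 0.0019, lost at adjusted p = 0.33 with an estimated correlation), with the cholesterol transporter gene Npc1 at -1.20.

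Genes typical of particular cell types also moved. Among 12 conventional dendritic cell genes, 5 fell late with Lps (median -0.83, adjusted p = 0.022, lost at adjusted p = 0.31 with an estimated correlation), and the lectin genes Mgl2 and Clec4a2 stood at -2.61 and -2.51. In unstimulated cells the same list fell over 24 h by a median of -0.59 (p = 0.042, lost at adjusted p = 0.64 with an estimated correlation). Late falls were 5 with Pam, 4 with Cpg and 4 with Grd (p = 0.0051, 0.044 and 0.0079, lost at adjusted p = 0.21, 0.38 and 0.24 with an estimated correlation). Of 12 macrophage markers, 3 rose and 6 fell late with Pam, with Marco up by 7.01 and C1qa, a complement gene, down at -2.50. As a list they were not called by limma camera (adjusted p = 0.16). Of 13 neutrophil markers, 5 fell late with Lps, led by the lactoferrin gene Ltf at -2.82 (p = 0.0023, 0.045 as adjusted p with an estimated correlation). Lists for B cells, T cells and natural killer cells (3 genes each), plasmacytoid dendritic cells (6), mast cells and basophils (4), erythroid cells (1) and stromal cells (3) were not called in any ligand window. In them Blnk rose by 1.84 in the middle Lps window, Cd247 at least 2.39-fold, Klrk1 by 1.14, Tcf4 by 2.67 and Hdc at least 14.8-fold, the erythroid gene Klf1 stood at 0.01, and Dcn rose by 1.68 late.

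Unstimulated arrays also changed over 24 h in culture, with 1 array per time. The 0 and 1 h arrays lay in plate column 10, those of 2, 4 and 8 h in column 11, and those of 6, 12 and 24 h in column 12. A change with time in culture thus cannot be told apart from an effect of place. Arg2, an arginase gene, rose by 2.62 ± 0.44 on the log2 scale, from 27.4 at 0 h to 163 at 24 h, and Il12b by 2.25 ± 0.49. The chemokine gene Ccl2 fell by 5.04 ± 1.08, from 944 to 44.4, and the cytokine-signalling inhibitor gene Cish fell by 4.42 ± 0.92, from 1126 to 72.7 (adjusted p in limma from 0.036 to 0.04). Slope tests called 135 genes higher and 208 lower, with 3772 at an unadjusted p under 0.05. With the slope on hours the balance turned, with 194 higher and 158 lower. Leaving out 1 array moved the number called. Without the 1 h array limma called 0 genes (3098 at an unadjusted p under 0.05) and without the 12 h array 0 (3388). The count was 82 without the 2 h array, 4 without the 4 h array, 5 without the 8 h array and 4 without the 24 h array, with 3308, 3586, 3699 and 2741 at an unadjusted p under 0.05. Ribosomal protein genes had a median slope of 0.11 over 24 h (limma camera, adjusted p = 0.00064). Their mean stood at 0.094 in the 24 h array and between -0.037 and 0.005 in the others, so this slope leans on 1 array. Endoplasmic reticulum stress genes had a median slope of -0.48 (limma camera, adjusted p = 0.019). Lysosome genes had one of 0.39 (limma camera, adjusted p = 0.0044), macrophage markers of 0.68 (adjusted p = 0.045) and conventional dendritic cell genes of -0.59 (adjusted p = 0.042). Dendritic cell maturation genes (limma camera, adjusted p = 0.04), negative feedback regulators (adjusted p = 0.042), chemokines (adjusted p = 0.045) and MHC class I presentation (adjusted p = 0.045) were lower, at medians of -0.52, -0.85, -0.22 and -0.40. All these list calls were lost, at adjusted p = 0.73 for macrophage markers and 0.64 for the others with an estimated correlation.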

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

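The tests of explanations below and the regroupings of arrays were chosen only after the results were seen, while the rules that picked out these results were planned.

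Conventional dendritic cell genes, 12 measured, stood higher in the first 2 h than at 12 to 24 h with 3 ligands, and were picked out because the list was called upward early and downward late. With an estimated correlation these calls were lost, at adjusted p = 0.26 and 0.38 for Cpg early and late, 0.28 and 0.31 for Lps, and 0.25 and 0.21 for Pam. The mean difference was 1.06 with Cpg, 1.26 with Lps and 1.23 with Pam, with 11, 11 and 10 of the 12 genes in this direction. The test of this difference ran on a list already called in opposite directions, so its p is no separate evidence and is left out. The list mean also went from 0.241 at 1 h to -1.103 at 16 h with Grd and from 0.222 at 1 h to -1.008 at 24 h with Pic, where it was not called early. In unstimulated cells the same list fell over 24 h by a mean of -0.678 (median -0.593, camera p = 0.042, lost at adjusted p = 0.64 with an estimated correlation), and a change with time in culture was not separated from one with ligand. The early rises alone were lost when each array was centred on its median.

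Interferon-stimulated genes, 42 measured, stood lower late with Pam than with each other ligand, and were picked out because the list was called upward with each of these ligands and downward with Pam. With an estimated correlation the calls for Cpg, Grd and Pam were lost, at adjusted p = 0.072, 0.16 and 0.62. The mean difference from Pam was 2.08 with Lps, 2.63 with Pic, 1.345 with Cpg and 1.12 with Grd, in 42, 42, 42 and 41 genes. This test too ran on opposite calls already seen, so its p is left out.

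Whether these genes fall below the unstimulated level with Pam stays open. The late median of -0.31 in 31 of 42 genes became -0.109 in 22 of 42 with the 12 and 24 h arrays of Pam against the unstimulated arrays of these times, -0.195 in 28 of 42 with the 16 h Pam arrays alone left out, and -0.23 in 26 of 42 with a linear trend in the unstimulated arrays, so a drift of the unstimulated cells cannot be told apart from an effect of Pam, because the corrections differ and the arrays of 12 and 24 h number 2. Scaling between arrays is argued against, since centring each array left a median of -0.269.

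Of 49 tests for a single array far from its group, 2 were met, where chance gives about 1 in 20 each. The ribosomal list in the unstimulated 24 h array lay at 0.094, against -0.037 to 0.005 in the other 7, a gap of 0.682 of the full range. Il6 in the unstimulated 2 h array was 62.4, against 20 to 33.3, a gap of 0.556 of the range on the log2 scale.

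The same arrays were split in 100 ways, the real one included, for every comparison with unstimulated cells. Only 1 split called as many genes as the real one, the real one itself, or 2 for Grd early. Random splits thus seldom reached the real counts. Chance is not excluded by this, because single arrays were moved although arrays of a group may not be independent. No adjustment over the comparisons was made either. Real counts and the highest of the other splits were 196 and 0, 1605 and 852, and 954 and 549 for the early, middle and late Lps windows. They were 78 and 59, 811 and 513, and 892 and 462 for Pic, and 238 and 117, 787 and 388, and 668 and 291 for Pam. For Cpg they were 213 and 0, 1149 and 648, and 792 and 3, and for Grd 96 and 123, 890 and 557, and 702 and 268.

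Under the same limits the ligand pairs had 1 such split, the real one, or 2 for Lps and Grd and for Cpg and Grd. With the times of the unstimulated arrays reassigned, the real 343 genes of the trend stood against at most 1. This does not separate time from place, as the plate column of these arrays was tied to time. Real and highest other counts were 390 and 328 for Lps and Pic, 648 and 316 for Lps and Pam, 49 and 10 for Lps and Cpg, and 210 and 301 for Lps and Grd. They were 867 and 0 for Pic and Pam, 360 and 70 for Pic and Cpg, 424 and 17 for Pic and Grd, 318 and 185 for Pam and Cpg, 155 and 0 for Pam and Grd, and 43 and 98 for Cpg and Grd. The splits above the real count, in Grd early and in the Lps and Cpg pairs with Grd, point to other structure among the samples, which was not tested.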

How the results depend on the processing

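The tests without genes at the floor and with 2 arrays left out together were chosen only after the results were seen; all other settings were planned.

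Of the settings tried on the main counts, 638 values stayed within 1.5 times and 53 did not. Among named genes 72616 comparisons kept their status, which includes genes called in neither run. Of these, 38123 came from leaving out 1 array. A further 558 were weaker, 348 stronger and 1 reversed. The reversed one was Tlr8 in Grd early vs unstimulated, at -1.21. It was 0.24 at 1 and 2 h against unstimulated arrays of the same times (adjusted p = 0.6 in limma), a setting that also leaves out 0.5 h. Without 0.5 h alone it was -0.58. An estimated correlation ended 141 of the list calls, and centring each array ended 22, among them the early dendritic cell and middle ribosomal lists. The erythroid list had no member left under the filter on dim probe sets and was not run there. Leaving out 1 array moved the ligand counts within 1572 to 1662 for Lps in the middle window and 70 to 121 for Pic early, and no total of a ligand or pair by over 1.5 times. The lower counts moved further early, for Pic from 24 to between 13 and 42, and for Grd from 18 to between 11 and 31, in each case without the unstimulated 24 h or 2 h array. The replicate number as a block moved no count by over 1.5 times. Replicate differences of 903 pairs of groups correlated with a median of 0.008, from -0.327 to 0.349, with 17.4% of pairs over 0.1. The median speaks against a pairing shared by all groups. It cannot exclude pairing within a ligand, because most pairs of groups are of different ligands. The floor of 20 bounds the size of changes for dim genes, and the cause of the shifts below was not tested except where the setting itself shows it.

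With the adjusted p alone the early, middle and late counts were 5480, 7807 and 6617 for Lps, 4735, 7311 and 6891 for Pic, 5690, 6617 and 5831 for Pam, 4924, 7341 and 5701 for Cpg, and 3975, 6783 and 6105 for Grd. The pairs gave 5144 for Lps and Pic, 6256 for Lps and Pam, 3002 for Lps and Cpg, 5097 for Lps and Grd, 6204 for Pic and Pam, 5195 for Pic and Cpg, 5424 for Pic and Grd, 5104 for Pam and Cpg, 3298 for Pam and Grd, and 2830 for Cpg and Grd. Without a minimum difference the balance of higher and lower genes turned in many comparisons. Early it was 1937 higher and 3543 lower for Lps, 1867 and 2868 for Pic, 1955 and 3735 for Pam, 1524 and 3400 for Cpg, and 1600 and 2375 for Grd, against a majority of rises among 2-fold changes. Pam had 3413 genes above and 1691 below Cpg, and 2022 above and 1276 below Grd, and Lps had 2063 above and 4193 below Pam, each against the 2-fold counts. With treat the counts were 2504 for Lps, 1316 for Pic, 1831 for Cpg and 1359 for Grd in the middle window, 59 and 1439 for Pic early and late, 999 for Lps and Pam, and 548 for Pic and Cpg. On log2(value + 16) Cpg and Grd differed in 21 genes. Pic early had 48 with array weights, 33 with matched times, which leave out 0.5 h (98 without 0.5 h alone), and 30 with a linear trend in the unstimulated arrays, where Lps early had 146, Pam early 165 and Grd early 69. Without 0.5 h the early counts were 387 for Lps, 430 for Pam and 402 for Cpg, and without 2 h 136 for Lps and 144 for Cpg.

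The unstimulated trend had 627 genes with the spread of all 96 arrays and 542 without genes at the floor. Without 1 array limma called 0 to 353, with 82 without 2 h, 5 without 8 h, 4 without 4 h, 4 without 24 h, and 0 without 1 h or 12 h (3098 and 3388 at an unadjusted p under 0.05).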

Other observations

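The tests of explanations in this part were chosen only after the results were seen, and the counts by window were planned.

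Interferon-stimulated genes had their lowest late values at 16 h with Cpg, Grd and Pam. With Pam their mean was 0.004 at 12 h and -0.534 at 16 h. Cpg had 1 array at 16 h, and unstimulated cells had none. Cxcl10 stood at 1827.2 and 1588.1 on the 12 h arrays of Cpg, at 49.9 on its 16 h array and at 119.3 at 24 h. With Grd it went from 1261.7 and 986.9 to 48.6 and 52.1, then to 109 and 94.4. With Pic it was 4462.4 and 4584.6 at 16 h and with Lps 1732.6 and 1725. The mean of the interferon-stimulated genes with Grd was 1.417 and 1.329 at 12 h, 0.303 and 0.34 at 16 h and 0.603 and 0.594 at 24 h. The cholesterol biosynthesis mean with Grd went from -0.926 and -0.845 to -0.326 and -0.339, then to -0.863 and -0.857. No test of the change between these times was run.

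In the first 2 h Pic had 87 genes lower than with Lps and 4 higher, 94 lower than with Pam and 5 higher, 123 lower than with Cpg and 6 higher, and 18 lower than with Grd and 2 higher. Grd differed from Lps in 27 genes, from Pam in 30 and from Cpg in 47, and Lps, Pam and Cpg differed from each other in 4 to 8. At 12 to 24 h Pic and Pam differed in 483 genes higher with Pic and 407 higher with Pam, and Cpg and Grd in 12 each way.

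At 0.5 h 51 genes were called lower with each of Lps, Pic, Pam and Grd, with Tlr8 at -2.38, -2.80, -2.47 and -2.48 and with Cpg at -0.70, and part of this overlap may come from the shared unstimulated arrays. An effect of time alike for every ligand was first tested by the number of genes higher in Cpg than in the mean of the other ligands. It was 40 of all 10543 tested, against 26 for Pam set against its own other ligands, which decided nothing under its bound. This test was then replaced, with that outcome known, by a sharper one over 69 genes called lower in Lps and Pic. There Cpg, singled out because its falls were few, stood 0.813 above Pam and Grd, higher in 68, past the adjusted p in 54 and called in 22. The falls were thus smaller with Cpg. An effect of time alike for every ligand stays undecided, because the Cpg arrays lie elsewhere on the plate and a place effect added to it could give the same difference. Drift of the unstimulated arrays as the main source is argued against, since the median was -1.271 against the 0 and 1 h arrays alone and -1.424 against all 8. That 51 of 51 genes were lower adds little, because they were chosen against a baseline that holds these arrays. Tlr8 itself rose in unstimulated cells, from 168 at 0 h to 601 at 24 h, so the pooled baseline may enlarge its fall. A place effect cannot be told apart, because 0 arrays of the first plate column are of another time and the Cpg 0.5 h arrays lie in column 10. The same holds at all times, as place is tied to time and ligand across the plate.

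The first Cpg 1 h array and the unstimulated 6 h array deviated alike from their neighbours, with a correlation of 0.631 across 10543 genes, which are not independent, Plet1 standing at -3.14 and -4.03 and Cish at -1.90 and -2.13. A swap of the samples is argued against, since the immediate-early and inflammatory mean in the unstimulated array was -0.113, within -0.17 to 0.295 in the other 7, and lower STAT5 signalling stays undecided, with STAT5 targets at the percentiles 34.35 and 0.13 of random lists. More macrophages and fewer dendritic cells may be part of it, as an open hypothesis tested on marker means: macrophage markers were higher by 0.619 and 0.48, against at most 0.397 between other replicates, and conventional dendritic cell genes stood at -0.267 and -0.41, against 0.168 in size. The macrophage markers moved unevenly. C1qc stood at 1.14 and 0.735, the brightest marker Lyz2 at 0.045 and 0.074, and Mrc1, the only one lower in either array, at 0.213 and -0.191. Lists not named by this hypothesis also passed other replicates in both arrays, with interferon-stimulated genes at 0.472 and 0.435 (at most 0.233 elsewhere), Toll-like receptor genes at 0.265 and 0.199 (0.13), lysosome genes at 0.183 and 0.178 (0.099) and, downward, endoplasmic reticulum stress genes at -0.152 and -0.143 (0.084) and oxidative phosphorylation at -0.136 and -0.083 (0.079). A shift like that with time in culture also stays open and was not tested. On principal component 3 the unstimulated 6 h array stood at 26.23. The unstimulated 4, 8, 12 and 24 h arrays stood at 9.75, 14.91, 20.19 and 25.65. Of these, 4 and 8 h lay in plate column 11, while 12 and 24 h lay in column 12, as did 6 h. An effect of place thus also stays open for the unstimulated 6 h array. Both Cpg 1 h arrays lay in column 11, so the column does not separate them. The Cpg 1 h arrays stood at -2.87 and -13.81. Macrophage, lysosome, conventional dendritic cell and endoplasmic reticulum stress lists moved as in the unstimulated trend, whose fit includes the 6 h array. Interferon-stimulated genes went the other way (trend median -0.23). Leaving out both arrays moved no count by over 1.5 times.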
